A study of Mus musculus with 24 samples.

How the data were processed

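Total RNA of mouse embryonic fibroblasts, connective tissue cells grown in culture from embryos of day 13.5, was sequenced in 24 libraries. Per the labels, the cells were wild type (WT) or carried alterations of Vhl, of Rassf1a or of both (Vhl/Rassf1a), and each of these 4 genotypes has 3 libraries named Cre, given as knockout, and 3 named GFP, given as control. The labels state neither how Cre or GFP was delivered, nor which exons were altered, nor how many embryos or cultures the libraries came from. If the 3 libraries of a group share a culture, p-values measure only the spread between these samples, which may be technical. Groups and replicate numbers were taken from the sample titles. The design note of the series instead speaks of single cells of kidney tubule epithelium, and the sample labels were followed.

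The deposited table holds raw read counts for 45706 Ensembl gene IDs in each library, and its values are whole numbers. RNA was extracted with the NucleoSpin RNA kit and libraries were made with a TruSeq Stranded kit, per the labels' protocols. Reads were trimmed with Trimmomatic 0.38, aligned with STAR 2.5.2b and placed on GRCm38, per the submitters' processing notes. The counting tool, its strand setting and the annotation are not given in the sources used here, so reads of overlapping, antisense or near-identical genes could not be told apart. Symbols, coordinates and transcripts came from the GENCODE M21 annotation of GRCm38, which named 45143 of the IDs and left 563 without a symbol.

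Library totals ran from 29.9 to 55.8 M counts. Genes were kept by the filterByExpr function of edgeR 4.0.16 on the 8 groups, with a minimum count of 10 and a minimum total of 15, which left 16573 genes. One quasi-likelihood model (glmQLFit and glmQLFTest) with 1 mean per group, TMM normalization and 16 residual degrees of freedom was fitted to all 24 libraries in R 4.3.3. The common biological coefficient of variation was 7.73%. The p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, with a threshold of 0.05, and 12 comparisons were made. They were Cre against GFP in each of 4 genotypes, 5 differences of these Cre effects between genotypes, and 3 comparisons of GFP libraries between an altered genotype and WT. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. CPM values, counts scaled to library size, used TMM library sizes and are given as mean and SD of 3 libraries. Adjusted p-values of genes are from this edgeR test unless another tool is named.

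In all, 38 lists of genes were written. They cover hypoxia-responsive glucose transport and glycolysis, other hypoxia-responsive genes, transcripts raised in clear cell renal cell carcinoma (ccRCC), p53 targets, DNA repair, DNA replication, mitosis and spindle, interferon-stimulated genes, antigen presentation, secreted inflammatory factors, YAP targets, extracellular matrix, contractile genes, nuclear and mitochondrial genes of oxidative phosphorylation, cholesterol synthesis, fatty acid metabolism, amino acid response, unfolded protein response, heat shock, NRF2 targets, immediate early genes, ribosomal proteins, ribosome biogenesis, core histones, the neighbours of Vhl and of Rassf1, sex-linked genes, and markers of macrophages, endothelium, epithelium, skeletal muscle, cartilage, fat, neural cells, mesothelium, fibroblasts and erythroid cells. Of their 780 genes, 778 were in the table and 715 were tested. The erythroid list had fewer than 5 tested members and was left out, so 37 lists were tested. The test was camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. An estimated correlation was run beside it, as was fry, which asks whether the members move one way on balance. The count of members past the threshold is given over all genes and, beside it, adjusted over the list alone. List tests between GFP libraries were not among those laid down for lists.

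Genes named in the text were Vhl and Rassf1; in each Cre against GFP comparison the 8 highest and the 8 lowest log2 fold changes past the threshold with a mean CPM of at least 5, no overlap of Cre and GFP values and a symbol that is not a clone name; up to 4 members of each list with the smallest adjusted p; and in each difference of Cre effects the 6 highest and the 6 lowest, without the overlap condition. Any other gene is said to have been chosen after its values were seen. The groups, comparisons, tests, gene lists, naming rule and alternatives were fixed before the data were examined.

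The alternatives were size factors of DESeq2 in edgeR, the Wald test of DESeq2 1.42.0, no filter beyond a total of 1 count, a fit of only the groups compared, a minimum log2 change of 1, a replicate block, each library left out in turn, and for lists an estimated correlation, fry and ranks of DESeq2 statistics. A pair of alternatives was added after the data were seen. One left out 2 GFP libraries that stood apart, and the other corrected library offsets for the GC content of each gene's longest transcript by a smooth curve.

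The steps were tested on simulated counts of 16573 genes, with known changes seeded in 50 genes at each fold. The seeded genes were drawn above a floor of mean CPM, so recovery of genes with very low counts was not tested. Counts were drawn gene by gene, without deviations shared by genes of like GC content, so recovery in the real data may be lower. For Rassf1a Cre against GFP, edgeR recovered 50% of seeded genes at a fold of 1.25, 92% at 1.5, 98% at 2 and 100% at 4, and called 6 unchanged genes. For the difference between Rassf1a and WT it recovered 22%, 68%, 82% and 98% at these folds. Overlaps of called genes between genotypes were set beside the product of both counts divided by the genes tested, per direction. These comparisons share no libraries.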

Results

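Gene expression was measured by RNA sequencing in 24 libraries of mouse embryonic fibroblasts, with 3 Cre and 3 GFP libraries in each of 4 genotypes, WT, Vhl, Rassf1a and Vhl/Rassf1a. The cell type is that of the sample labels, since the design note of the series names kidney tubule epithelium instead. The series concerns how loss of Vhl and Rassf1a relates to DNA damage, chromosomal instability and the expression profile of ccRCC, the most common kidney cancer. Library totals were 29.9 to 43.3 M counts in WT GFP, 34.7 to 38.8 in WT Cre, 34.7 to 43.5 in Vhl GFP and 35.0 to 43.2 in Vhl Cre. They were 34.9 to 41.6 in Rassf1a GFP, 38.1 to 55.8 in Rassf1a Cre, 32.9 to 43.2 in Vhl/Rassf1a GFP and 34.7 to 53.2 in Vhl/Rassf1a Cre. Each library had counts for 21350 to 23770 genes, and replicates correlated across genes at 0.989 to 0.995 on the log2 CPM scale, where genes are not independent replicates. No pair of replicates agreed within sampling noise, since the chi-square of their counts over its degrees of freedom was at least 3.06. A pair of GFP libraries stood apart from the others of their groups, Rassf1a GFP replicate 1 and Vhl/Rassf1a GFP replicate 2. Their deviations from the other libraries of their groups correlated with each other at 0.776 across 12900 genes. With the GC content of the genes these deviations correlated at 0.729 and 0.753. In groups without these libraries such correlations ran from -0.436 (Vhl Cre replicate 1) to 0.483 (WT GFP replicate 3), so GC-linked deviations were not confined to them.

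The targeted genes came first. Vhl (ENSMUSG00000033933, GRCm38 chromosome 6, 113623959 to 113631633) encodes the part of a ubiquitin ligase that recognises the alpha subunits of hypoxia-inducible factors for breakdown. Its level fell in Vhl cells from 26.7 CPM ± 0.972 with GFP to 2.57 CPM ± 0.257 with Cre (SD, n = 3 each), and in Vhl/Rassf1a cells from 22.0 CPM ± 1.59 to 2.10 CPM ± 0.523. These are log2 fold changes of -3.38 (SE 0.11, adjusted p = 9.84e-17) and -3.42 (SE 0.11, adjusted p = 1.34e-16), or 90.4% and 90.7% lower levels. In WT cells Vhl was at 23.4 CPM ± 0.948 with GFP and 23.7 CPM ± 0.862 with Cre, and in Rassf1a cells at 26.7 CPM ± 2.49 and 25.7 CPM ± 0.698.

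Rassf1 (ENSMUSG00000010067, GRCm38 chromosome 9, 107551555 to 107562267) encodes a Ras association domain protein whose longer form, Rassf1a, binds microtubules and Hippo pathway kinases. In libraries labelled Rassf1a Cre its level was 26.6 CPM ± 1.249, against 27.9 CPM ± 2.90 with GFP (log2 fold change -0.07, SE 0.09, adjusted p = 0.998). Gene counts include every form of Rassf1 and exons outside any altered part, so this value does not check the label. Rassf1 rose with Cre in Vhl cells, from 26.6 CPM ± 2.49 to 43.8 CPM ± 1.00 (log2 fold change 0.72, SE 0.09, adjusted p = 9.51e-07), and in Vhl/Rassf1a cells, from 32.6 CPM ± 3.95 to 45.2 CPM ± 2.11 (0.47, SE 0.09, adjusted p = 0.000281).

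**Figure D1:**
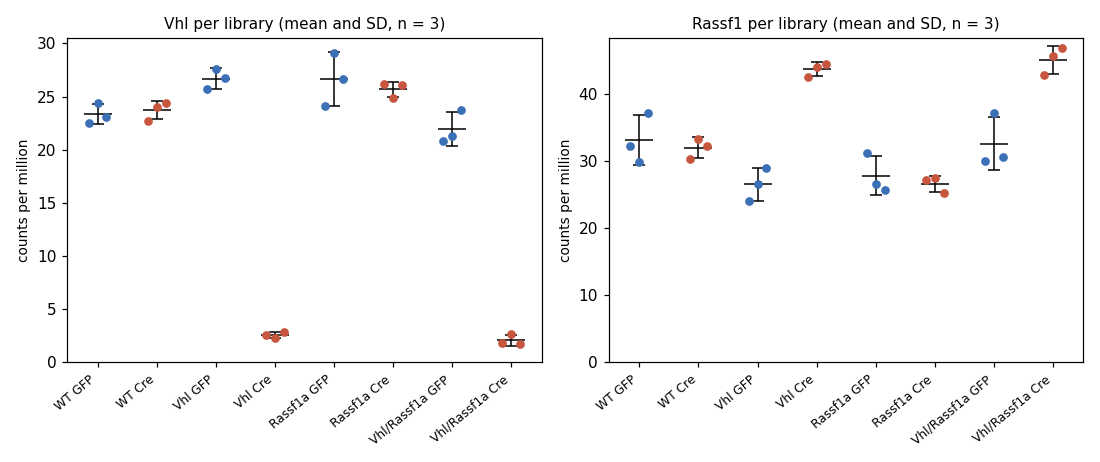
CPM of Vhl and of Rassf1 in each of the 24 libraries, GFP in blue and Cre in red, with the mean and SD of 3 per group. Vhl is at 2.57 and 2.10 CPM in Vhl Cre and Vhl/Rassf1a Cre.

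Cre against GFP in WT cells shows how these libraries differ where no gene is named as altered, and holds any effect of Cre, of GFP and of their delivery. Secreted and matrix genes rose with Cre: Dpt and Dcn, small proteins that organise collagen, had log2 fold changes of 1.12 (SE 0.17) and 0.80 (SE 0.13), and Serpina3n, a secreted protease inhibitor, one of 1.13 (SE 0.18). The lists for secreted inflammatory factors, extracellular matrix and fibroblast markers rose, with medians of 0.11, 0.11 and 0.24. Of their 28, 31 and 14 members, 5, 6 and 3 rose over all genes and 8, 11 and 7 adjusted over the list alone, and none fell (camera adjusted p = 9.58e-08, 5.28e-12 and 3.17e-08). Examples were the chemokine Ccl2 (0.31) and the matrix protein Thbs2 (0.35). Eml5, a microtubule-associated protein, fell from 76.9 CPM ± 16.6 to 4.39 CPM ± 0.718 (SD, n = 3 each; log2 fold change -4.13, SE 0.15), and Mkrn2, a RING finger protein, fell from 87.2 CPM ± 1.94 to 12.0 CPM ± 0.273 (-2.86, SE 0.12). Htra2, a mitochondrial protease, and Ifrd2 fell by 0.99 and 0.98 on the log2 scale.

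In WT cells 138 genes rose and 71 fell with Cre, 209 in all, of which 8 rose and 20 fell at least 2-fold. The count was 87 without WT GFP replicate 1, 108 without WT GFP replicate 3, 124 without WT Cre replicate 2 and 103 without WT Cre replicate 3. GC-corrected offsets gave 535. With an estimated correlation the 3 list calls above had adjusted p = 0.00148, 0.0415 and 0.00079. Another 2 lists were past the threshold. They were ccRCC transcripts (median 0.08, 1 of 23 members rose and 2 adjusted over the list alone; adjusted p = 0.0111, and 0.291 with an estimated correlation; 0.0613 without WT Cre replicate 2) and immediate early genes. The latter (median -0.09, 0 of 21 members called either way; adjusted p = 0.0271, and 0.937 with an estimated correlation) had 0.100 without WT Cre replicate 1, 0.0557 without WT GFP replicate 1 and 0.483 without WT GFP replicate 3.

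In Vhl cells, genes of the hypoxia response rose with Cre. Car9, a carbonic anhydrase of the cell surface, rose from 2.56 CPM ± 0.232 to 68.1 CPM ± 0.165, Ndufa4l2, a mitochondrial protein, from 6.50 CPM ± 0.379 to 134.8 CPM ± 11.7, and Egln3, an oxygen-dependent prolyl hydroxylase, from 16.7 CPM ± 0.438 to 203.8 CPM ± 5.57 (SD, n = 3 each). Their log2 fold changes were 4.73 (SE 0.12, adjusted p = 3.63e-18), 4.38 (SE 0.16, adjusted p = 1.09e-15) and 3.61 (SE 0.06, adjusted p = 8.51e-21). Among genes named by rule, with a mean CPM of at least 5, the largest increases were in Atp7b, a copper transporter (log2 fold change 6.27, SE 0.21), H2-Ab1, a chain of major histocompatibility complex class II (5.70, SE 0.17), and A2m, a protease inhibitor (5.47, SE 0.20). Mgarp and Cox4i2, proteins of mitochondria, and the receptor Gpr35 rose by 4.74, 4.34 and 3.76. Il1rn, the secreted antagonist of the interleukin-1 receptor, fell from 214.6 CPM ± 30.6 to 21.7 CPM ± 0.521 (-3.30, SE 0.13), and Islr, an immunoglobulin-domain matrix protein, fell by 2.65 on the log2 scale.

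Glucose transport and glycolysis genes rose together in Vhl cells, with 20 of 21 members higher and 1 lower over all genes, and the same counts adjusted over the list alone (median 1.18; camera adjusted p = 4.68e-67, and 0.000261 with an estimated correlation). Pfkp and Pfkfb3, enzymes that set the pace of glycolysis, rose by log2 fold changes of 2.01 and 1.94, Pdk1, a brake on pyruvate entry into mitochondria, by 2.00, and Pgk1 from 457.2 CPM ± 24.0 to 1366 CPM ± 47.5. The member that fell was the enolase Eno2 (-1.10), a gene chosen after its values were seen. Of 35 other hypoxia-responsive genes, 32 rose and 0 fell, by either adjustment (median 1.32; adjusted p = 5.39e-123, and 8.58e-10 with an estimated correlation). Among 23 transcripts raised in ccRCC, 11 rose and 5 fell, by either adjustment (median 0.19; adjusted p = 5.96e-17, and 0.000174 with an estimated correlation). On ranks of DESeq2 statistics the adjusted p of this list was 0.0819. Its leading members, Egln3, Pfkp, Car9 and Ndufa4l2, are also hypoxia-responsive.

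Cell division genes were lower with Cre in Vhl cells. Of 35 mitosis and spindle genes, 34 fell and 0 rose, by either adjustment (median -0.81; adjusted p = 9.94e-33, and 0.000468 with an estimated correlation). The cyclins Ccnb1 and Ccnb2, which drive entry into mitosis, fell by 0.99 and 1.07 on the log2 scale, the checkpoint kinase Bub1b by 0.95 and the spindle motor Kif23 by 0.83. Of 35 DNA repair genes, 23 fell and 0 rose over all genes, 25 and 1 adjusted over the list alone (median -0.29; adjusted p = 0.000106, and 0.0113 with an estimated correlation), led by the Fanconi anaemia genes Fanci (-1.13) and Fanca (-0.82). Of 30 DNA replication genes, 22 fell and 1 rose, 23 and 1 adjusted over the list alone (median -0.32; adjusted p = 0.000136, and 0.100 with an estimated correlation), with Mcm10 at -0.70 and Uhrf1 at -0.69. Of 25 p53 targets 6 rose and 6 fell, 8 and 8 adjusted over the list alone (adjusted p = 0.921). Of 17 core histone genes 9 rose and 0 fell, by either adjustment (median 0.62; adjusted p = 0.0263, 0.104 with an estimated correlation and 0.0804 with GC-corrected offsets).

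Interferon-stimulated genes, which cells express in defence against viruses, were lower with Cre in Vhl cells. Of 34, 33 fell and 0 rose over all genes and 34 fell adjusted over the list alone (median -1.51; adjusted p = 2.33e-11, and 0.303 with an estimated correlation). Ifit1 fell from 78.1 CPM ± 13.3 to 12.5 CPM ± 3.82 (log2 fold change -2.65, SE 0.33), with Ifit3 at -2.62 and Iigp1 at -2.79. Of 15 antigen presentation genes 11 fell and 1 rose, by either adjustment (median -0.42; adjusted p = 0.0143, and 0.531 with an estimated correlation), among them Erap1 (-0.60), Nlrc5 (-1.09) and B2m (-0.36). Of 28 secreted inflammatory factors 8 rose and 14 fell, 10 and 14 adjusted over the list alone (adjusted p = 0.144), with the chemokine Cxcl5 at -2.02.

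Metabolic and stress lists also moved in Vhl cells. Of 26 amino acid response genes 19 fell and 2 rose, 21 and 2 adjusted over the list alone (median -0.46; adjusted p = 6.64e-07, and 0.0974 with an estimated correlation). The amino acid transporter Slc7a5 (-1.48) and the serine synthesis enzyme Psat1 (-1.01) fell, while Vldlr, a lipoprotein receptor, rose (2.56). Of 24 cholesterol synthesis genes 15 fell and 0 rose, 16 and 0 adjusted over the list alone (median -0.24; adjusted p = 0.00200, and 0.0534 with an estimated correlation). Of 23 NRF2 targets 12 fell and 3 rose, 13 and 3 adjusted over the list alone (median -0.18; adjusted p = 0.0486, and 0.481 with an estimated correlation). That call was lost without Vhl Cre replicate 1 (0.0563), Vhl Cre replicate 2 (0.0523) or Vhl GFP replicate 1 (0.127), with size factors of DESeq2 (0.0507), with GC-corrected offsets (0.0896) and in a fit of only the groups compared (0.117).

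Matrix genes and markers of other cell types changed as well in Vhl cells. Of 31 matrix genes 16 fell and 5 rose, by either adjustment (median -0.16; adjusted p = 0.00203, and 0.303 with an estimated correlation), with Eln, the core of elastic fibres, at -1.29 and Tnc at 0.68. Of 22 YAP targets 10 rose and 5 fell, 10 and 7 adjusted over the list alone (median 0.13; adjusted p = 0.0332, 0.341 with an estimated correlation, 0.274 on ranks of DESeq2 statistics and 0.0665 in a fit of only the groups compared), with Ankrd1 at 1.26. Epithelial markers rose in 6 of 9 members and fell in 0, by either adjustment (median 1.85; adjusted p = 6.24e-05, and 0.0616 with an estimated correlation), among them the keratins Krt19, from 33.8 CPM ± 0.896 to 122.2 CPM ± 9.60, and Krt18, from 3.41 CPM ± 0.436 to 12.4 CPM ± 0.889. Mesothelial markers, which share these keratins, rose in 4 of 8 (median 0.73; adjusted p = 0.00190, 0.0150 with an estimated correlation and 0.0601 on ranks of DESeq2 statistics). Skeletal muscle markers rose in 4 of 9 (median 0.63; adjusted p = 0.01004, 0.0478 with an estimated correlation and 0.152 on ranks of DESeq2 statistics), with the actin Acta1 at 2.02. Of 5 fat markers 2 fell (median -0.12; adjusted p = 0.00941, 0.0506 with an estimated correlation, 0.147 on ranks of DESeq2 statistics and 0.235 with no filter), the regulator Cebpa at -2.55 and the lipid droplet protein Plin4 at -1.41. These 3 lists had no member moving the other way, and the same counts adjusted over the list alone.

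The remaining 17 lists were not past the threshold in Vhl cells. Members that rose and fell over all genes were 6 and 3 of 20 contractile genes (adjusted p = 0.392), 3 and 6 of 35 nuclear oxidative phosphorylation genes (0.288). They were 0 and 8 of 13 mitochondrially encoded genes (0.0546), 6 and 11 of 28 fatty acid genes (0.144), 2 and 6 of 21 unfolded protein response genes (0.482). For others they were 4 and 6 of 16 heat shock genes (0.886), 11 and 4 of 21 immediate early genes (0.0945), 0 and 8 of 33 ribosomal protein genes (0.104) and 1 and 7 of 25 ribosome biogenesis genes (0.104). They were also 2 and 1 of 6 neighbours of Vhl (0.933), 3 and 2 of 11 neighbours of Rassf1 (0.978), where the median was above 0 and the test pointed down, and 3 and 1 of 5 sex-linked genes (0.392). Among cell type markers they were 1 and 1 of 6 macrophage markers (0.889), 6 and 2 of 11 endothelial markers (0.196), 0 and 5 of 12 cartilage markers (0.0750), 3 and 2 of 10 neural markers (0.612) and 1 and 5 of 14 fibroblast markers (0.218). Adjusted over the list alone, counts differed for immediate early genes (12 and 5), ribosomal proteins (0 and 7), sex-linked genes (4 and 1), cartilage (0 and 7) and fibroblast markers (2 and 5).

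Of the sex-linked genes, the Y-linked Ddx3y (0.51, SE 0.12, adjusted p = 0.00143), Eif2s3y (0.53, SE 0.13, adjusted p = 0.00215) and Uty (0.62, SE 0.20, adjusted p = 0.0170) rose in Vhl cells. Xist, which silences an X chromosome in female cells, fell (-0.62, SE 0.18, adjusted p = 0.00998). Uty and Xist move in opposite ways between male and female cells, so a test of the list in 1 direction does not cover such a shift. Whether the shares of male and female cells differ between Vhl GFP and Vhl Cre libraries was not tested. The Cre effects given for Vhl cells may hold such a difference. The call of Uty was lost without Vhl Cre replicate 1 (0.0542) or Vhl GFP replicate 3 (0.0593), and that of Xist without Vhl Cre replicate 2 (0.0644).

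With Cre in Vhl cells 2884 genes rose and 3107 fell, 5991 of 16573 in all, of which 755 rose and 415 fell at least 2-fold. Of the 18 list calls, 17 were kept with any 1 library left out and 7 held with an estimated correlation.

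**Figure D2:**
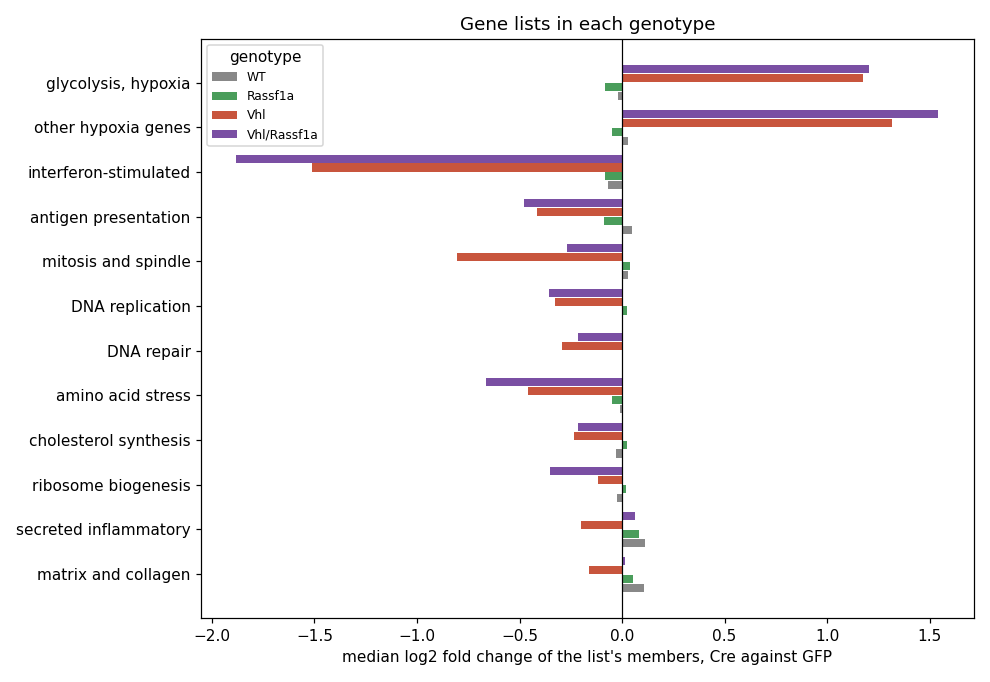
Median log2 fold change, Cre against GFP, of the members of 12 gene lists, with 1 bar per genotype. Mitosis and spindle genes are at -0.81 in Vhl and -0.27 in Vhl/Rassf1a cells.

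Cre effects in Vhl cells were also set against those in WT cells. Glycolysis and other hypoxia genes rose more, in 20 of 21 and 31 of 35 members (medians of the difference 1.19 and 1.49). Among 23 ccRCC transcripts the difference was past the threshold above 0 in 9 and below 0 in 5 (0.16; adjusted p = 6.04e-14, and 0.179 on ranks of DESeq2 statistics). Mitosis and spindle genes fell more in 34 of 35 (-0.82). For DNA repair genes the difference was below 0 in 14 and above 0 in 1 of 35 (-0.31). For secreted inflammatory factors it was below 0 in 15 and above 0 in 5 of 28 (-0.32), and for fibroblast markers below 0 in 6 of 14 (-0.35). Both of these lists rose with Cre in WT cells, which enters their difference. For mesothelial and skeletal muscle markers it was above 0 in 3 of 8 (0.71; 0.0690 on ranks of DESeq2 statistics) and 2 of 9 (0.59; 0.0699). Adjusted over the list alone these counts were 20 and 1, 31 and 0, 9 and 5, 0 and 34, 2 and 21, 5 and 16, 0 and 7, 4 and 0, and 2 and 0 members higher and lower. Among genes named by rule the largest differences were Atp7b (6.53, SE 0.46), H2-Ab1 (5.34, SE 0.37) and A2m (5.09, SE 0.57), and the lowest were Il1rn (-3.79, SE 0.17), Vhl (-3.40, SE 0.14) and Islr (-2.96, SE 0.21). The Cre effect differed between Vhl and WT in 3846 genes, 1773 higher and 2073 lower. Of 22 list calls, 19 were kept with any 1 library left out. The 9 described here held with an estimated correlation.

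In Rassf1a cells few genes changed with Cre. Among genes with a mean CPM of at least 5, those that fell included Eml5 (log2 fold change -3.68, SE 0.15, adjusted p = 1.77e-13), the membrane protein Tmem130 (-2.71, SE 0.20, adjusted p = 2.29e-08), Mkrn2 (-2.48, SE 0.12, adjusted p = 2.55e-12), Htra2 (-1.004, SE 0.11, adjusted p = 5.77e-06) and Ifrd2 (-0.85, SE 0.14, adjusted p = 0.00265), all of which also fell in WT cells. The genes that rose included Clca3a1 and Flt1. Clca3a1, a chloride channel accessory protein, rose by a log2 fold change of 0.40 (SE 0.07, adjusted p = 0.00733), and the vascular growth factor receptor Flt1 by 0.40 (SE 0.07, adjusted p = 0.00422). Ifrd2, Clca3a1 and Flt1 had adjusted p = 0.0582, 0.411 and 0.314 in a fit of only the groups compared, and Flt1 had 0.0503 without Rassf1a GFP replicate 2. Among 11 neighbours of Rassf1 on chromosome 9, Zmynd10 rose and Ifrd2 fell, 1 and 1 by either adjustment.

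Zmynd10, which encodes a protein needed to assemble the motors of cilia, rose from 0.131 CPM ± 0.0219 to 1.20 CPM ± 0.226 in Rassf1a cells (SD, n = 3 each; log2 fold change 3.17, SE 0.36, adjusted p = 1.62e-05). It also rose in Vhl/Rassf1a cells, from 0.276 CPM ± 0.0250 to 1.05 CPM ± 0.102 (1.91, SE 0.32, adjusted p = 6.04e-05). In WT cells it was at 0.371 and 0.207 CPM with GFP and Cre, and in Vhl cells at 0.235 and 0.347 CPM. Zmynd10 lies at 107547298 to 107551319 of chromosome 9 on the same strand as Rassf1, and ends 236 bases before Rassf1 starts. With Cre it had 37 to 78 counts per library in Rassf1a and 36 to 61 in Vhl/Rassf1a cells. With GFP it had 4 to 6 and 9 to 12, and in WT and Vhl libraries 4 to 24. This change beside Rassf1 bears on the Rassf1a label, but does not show what was altered, and its cause was not tested.

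In Rassf1a cells 31 genes rose and 34 fell with Cre, 65 in all, against 1093 at an unadjusted p under 0.05, and 5 rose and 15 fell at least 2-fold. The count was 40 without Rassf1a GFP replicate 1, 24 without Rassf1a GFP replicate 2, 31 without Rassf1a Cre replicate 1, 29 without Rassf1a Cre replicate 2 and 42 without Rassf1a Cre replicate 3. DESeq2 called 103 genes, a fit of only the groups compared 12, no filter 151, GC-corrected offsets 209, and the fit without the libraries that stood apart 112.

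No list call in Rassf1a cells held with an estimated correlation or with each library left out. Mitochondrially encoded genes had a median of 0.37 with 0 of 13 members called by either adjustment (adjusted p = 2.34e-05, 0.657 with an estimated correlation and 0.246 without Rassf1a GFP replicate 1, where this list was at -0.79 against the other libraries of its group). Glycolysis genes (median -0.08; adjusted p = 0.00297), nuclear oxidative phosphorylation genes (-0.05; 0.0137) and ribosomal proteins (-0.06; 0.00708) had 0.477, 0.815 and 0.559 without the same library, and 0.657, 0.657 and 0.748 with an estimated correlation. Without Rassf1a Cre replicate 1 the last pair had 0.124 and 0.131. Matrix genes (0.05; 0.00297) and secreted inflammatory factors (0.08; 0.00240) had 0.0668 and 0.0510 without Rassf1a GFP replicate 2, and 0.657 and 0.116 with an estimated correlation. In these 5 lists 0 members were called over all genes, and adjusted over the list alone 1 glycolysis gene fell and 4 inflammatory factors rose and 1 fell.

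The Cre effect differed between Rassf1a and WT cells in 1 gene by edgeR, Zmynd10 (difference 3.99, SE 0.55, adjusted p = 0.00494), which the naming rule takes as a neighbour of Rassf1 where Cre is set against GFP. In this difference it lies below the level set for naming, and was chosen after its values were seen. There were 544 genes at an unadjusted p under 0.05, and DESeq2 called 1. Without WT GFP replicate 2, and in a fit of only the groups compared, edgeR called 0 genes. With no filter it called 22, and without the libraries that stood apart 2. Of 13 list calls, 0 held with an estimated correlation and 3 were kept with any 1 library left out: matrix genes (median -0.07; adjusted p = 0.000424, and 0.304 with an estimated correlation), contractile genes (0.10; 0.000421, and 0.304) and fibroblast markers (-0.14; 0.00111, and 0.0585), with 0 members called by either adjustment.

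Double alteration again brought the hypoxia response. In Vhl/Rassf1a cells Car9 rose from 2.24 CPM ± 0.485 to 52.3 CPM ± 2.74, Ndufa4l2 from 5.93 CPM ± 1.28 to 159.8 CPM ± 7.39, and Atp7b from 0.254 CPM ± 0.165 to 20.3 CPM ± 2.18 (SD, n = 3 each; log2 fold changes 4.53, 4.74 and 6.24, SE 0.13, 0.16 and 0.21). Of 21 glycolysis genes 19 rose and 1 fell over all genes, 20 and 1 adjusted over the list alone (median 1.20; adjusted p = 1.42e-87, and 3.97e-05 with an estimated correlation), of 35 other hypoxia genes 34 rose by either adjustment (1.54; 2.64e-166, and 1.33e-10). Of 23 ccRCC transcripts 14 rose and 4 fell, 15 and 4 adjusted over the list alone (0.40; 6.79e-24, and 9.29e-06). Amino acid response genes fell in 23 of 26 and rose in 2 by either adjustment (-0.66; 5.82e-20, and 0.00506), with Slc7a5 at -1.85 and Mthfd2, a mitochondrial folate enzyme, at -1.29. Ribosome biogenesis genes fell in 21 of 25, 22 adjusted over the list alone (-0.35; 8.95e-10, and 0.00245), with Nat10 at -0.53 and the nucleolar helicase Ddx21 at -0.41.

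Interferon-stimulated genes fell in 34 of 34 members by either adjustment in Vhl/Rassf1a cells (median -1.88; adjusted p = 1.72e-19, and 0.128 with an estimated correlation), with Bst2 at -2.11. In Vhl/Rassf1a GFP replicate 2, one of the libraries that stood apart, this list was 0.80 above the other libraries of its group. DNA repair genes fell in 21 of 35, 23 adjusted over the list alone (-0.21; 8.04e-05, and 0.00593), and replication genes in 21 of 30, 23 with 1 rising adjusted over the list alone (-0.36; 1.65e-07, and 0.0299). Mitosis and spindle genes fell in 27 of 35, 28 with 1 rising adjusted over the list alone (-0.27; 2.51e-07, and 0.0767 with an estimated correlation), with Bub1b at -0.44 and Mki67, a mark of dividing cells, at -0.44. Of 5 fat markers 5 fell by either adjustment (-0.47; 0.000151, and 0.00588), including Cebpa (-1.53) and Fabp4 (-0.47). Krt19, Krt18 and Acta1, named above for Vhl cells, rose here as well, with log2 fold changes of 1.28, 0.85 and 1.33.

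In Vhl/Rassf1a cells 2466 genes rose and 2453 fell with Cre, 4919 in all, of which 598 rose and 209 fell at least 2-fold, and a fit of only the groups compared called 3008. Of 16 list calls, 13 were kept with any 1 library left out and 8 held with an estimated correlation. Against the Cre effect in WT cells 2454 genes differed, 1228 higher and 1226 lower, and 3990 with GC-corrected offsets. Among those named by rule the highest were Atp7b (6.50, SE 0.47), A2m (5.56, SE 0.61) and H2-Ab1 (5.39, SE 0.38) and, at the low end, Vhl (-3.44, SE 0.14), Isg15 (-2.84, SE 0.58) and Oasl2 (-2.67, SE 0.54), genes of the interferon response. Of 19 list calls in that difference, 16 were kept with any 1 library left out and 11 held with an estimated correlation, among them amino acid response (19 of 26 lower and 2 higher, 21 and 2 adjusted over the list alone; median -0.65) and ribosome biogenesis genes (14 of 25 lower, 16 adjusted over the list alone; -0.34). On ranks of DESeq2 statistics the adjusted p was 0.0793 for ccRCC transcripts (10 of 23 higher and 3 lower, 10 and 5 adjusted over the list alone; median 0.27) and 0.0732 for skeletal muscle markers (2 of 9 higher by either adjustment; 0.39), and with no filter 0.102 for the latter.

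The comparison of double with single alteration sets the Cre effect in Vhl/Rassf1a cells against that in Vhl cells. These genotypes already differed with GFP, as given below, and counts of Rassf1 did not check the Rassf1a label. What Rassf1a alteration adds therefore cannot be told apart here from the embryos or cultures used. Mitosis and spindle genes fell less in Vhl/Rassf1a than in Vhl cells: the difference of Cre effects was above 0 and past the threshold in 29 of 35 members, 31 adjusted over the list alone, and below 0 in none past it (median 0.54; adjusted p = 7.10e-44, and 0.000343 with an estimated correlation). Secreted inflammatory factors were higher in 8 and lower in 2 of 28, 12 and 3 adjusted over the list alone (0.33; 4.04e-05, and 0.00907 with an estimated correlation). Ribosome biogenesis genes were lower in 9 of 25, 16 adjusted over the list alone (-0.25; 7.60e-10, and 0.00393). Their level against WT GFP was -0.34 in Vhl GFP and -0.41 in Vhl Cre, and 0.02 in Vhl/Rassf1a GFP and -0.37 in Vhl/Rassf1a Cre, so the groups differed more with GFP than with Cre. Matrix genes were higher in 13 and lower in 1 of 31, 17 and 2 adjusted over the list alone (0.27; 6.31e-10, and 0.0531 with an estimated correlation). Among genes named by rule the highest differences were Il1rn (1.77, SE 0.17), the matrix protease Mmp3 (1.43, SE 0.17) and Pi15 (1.36, SE 0.31), followed by Mmp13 (1.23, SE 0.19) and Sned1 (1.22, SE 0.10). The lowest were the fast myosins Myh2 (-1.59, SE 0.12) and Myh1 (-1.52, SE 0.16), Apln, a vascular peptide hormone (-1.48, SE 0.12), and Sfrp2, a secreted Wnt antagonist (-1.37, SE 0.21).

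Of the other list calls in this difference, 4 were kept with any 1 library left out and lost with an estimated correlation, amino acid response genes (7 of 26 lower, 11 adjusted over the list alone; median -0.23; adjusted p = 4.48e-06, and 0.134), epithelial markers (3 of 9 lower, 5; -0.57; 0.000653, and 0.133), YAP targets (1 of 22 higher and 4 lower, 1 and 6; -0.14; 0.00152, and 0.182) and heat shock genes (1 of 16 lower, 2; -0.14; 0.00705, and 0.0520). The Cre effect differed in 1010 genes, 570 higher and 440 lower. The count was 1856 without the libraries that stood apart, 2261 with GC-corrected offsets and 631 in a fit of only the groups compared.

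The double effect was also set against the sum of the single effects, counted from WT. Mitosis and spindle genes fell less with Cre than the sum, so that the difference from it was above 0 (12 of 35 members higher, 30 adjusted over the list alone; median 0.49; adjusted p = 2.49e-28, and 0.00361 with an estimated correlation). The difference was also above 0 in secreted inflammatory factors (8 of 28 higher and 1 lower, 14 and 3; 0.38; 7.48e-06, and 0.00444), matrix genes (11 of 31, 17 and 1 lower; 0.33; 3.22e-12, and 0.0257) and fibroblast markers (3 of 14, 3; 0.26; 0.000435, and 0.0120). It was below 0 in ribosome biogenesis genes (4 of 25 lower, 8; -0.27; 1.79e-09, and 0.00444) and heat shock genes (1 of 16 lower, 2; -0.12; 0.00627, and 0.0346). For ribosome biogenesis the lower level in Vhl GFP given above enters this difference too. The Cre effect in WT cells is added in this difference. Inflammatory, matrix and fibroblast lists rose with Cre in WT cells (medians 0.11, 0.11 and 0.24), which enters their values. It also enters for genes named next, such as Serpina3n (1.13 in WT cells), Mmp3 (0.63) and Myh1 (-0.75). Among genes named by rule the highest were Il1rn (2.10, SE 0.24), Mmp3 (2.08, SE 0.24) and Serpina3n (1.95, SE 0.24), and the lowest Myh1 (-2.07, SE 0.23), Apln (-1.77, SE 0.18) and Myh2 (-1.73, SE 0.21). There were 329 genes above and 177 below the sum, 506 in all. The count was 336 without Rassf1a Cre replicate 1, 337 without Vhl/Rassf1a Cre replicate 3, 964 without the libraries that stood apart and 1345 with GC-corrected offsets.

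**Figure D3:**
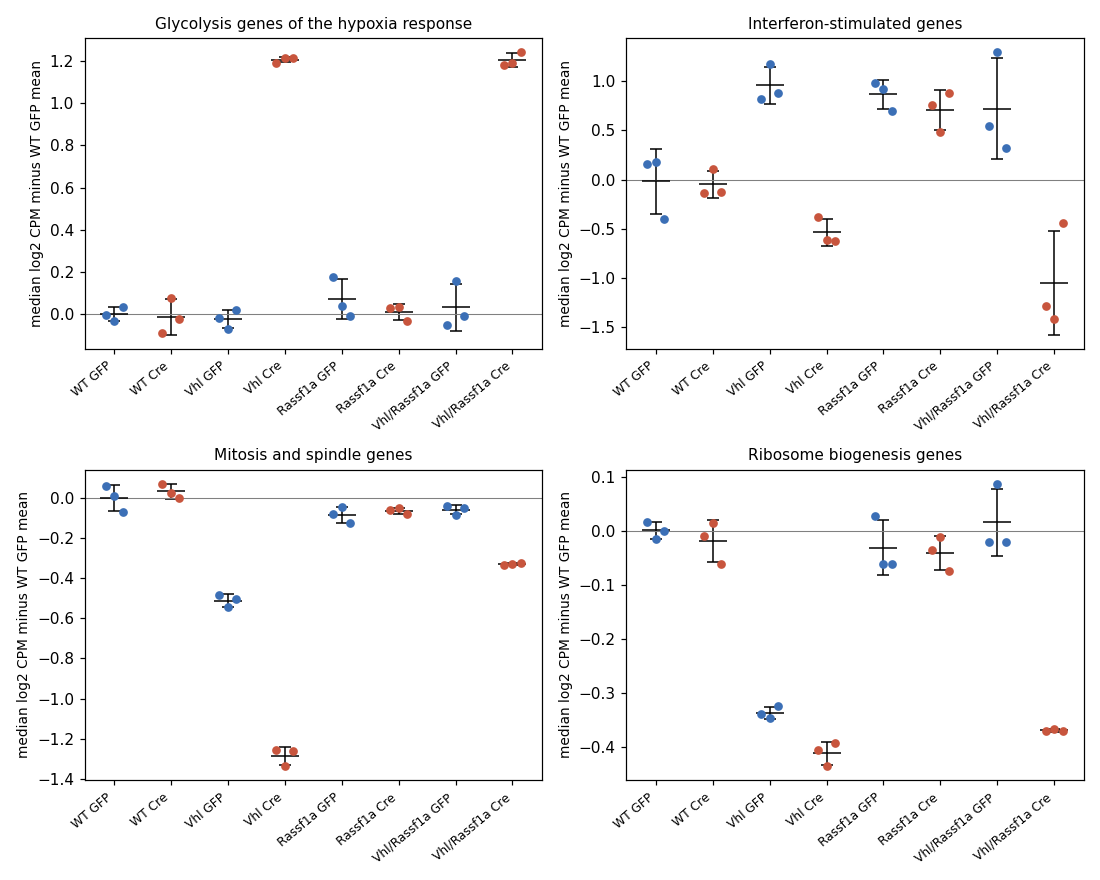
Median log2 CPM of the members of 4 gene lists in each library, minus the mean of WT GFP, with the mean and SD of 3 per group. The lists are hypoxia glycolysis genes, interferon-stimulated genes, mitosis and spindle genes, and ribosome biogenesis genes.

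The genotypes already differed with GFP, where Cre had not been given. Interferon-stimulated genes were higher than in WT GFP in 25 of 34 members in Vhl GFP, 21 in Rassf1a GFP and 20 in Vhl/Rassf1a GFP, 28, 29 and 27 adjusted over the list alone (medians 0.96, 0.85 and 0.78; adjusted p = 5.69e-06, 1.65e-07 and 8.90e-07, and 0.394, 0.516 and 0.830 with an estimated correlation). Against WT GFP the level of this list ran from 0.32 to 1.30 between Vhl/Rassf1a GFP libraries, where replicate 2 was 0.80 above the others. Mitosis and spindle genes were lower in 34 and higher in 1 of 35 in Vhl GFP by either adjustment (-0.50; 1.50e-20, and 0.00438), cholesterol synthesis genes lower in 19 of 24 by either adjustment (-0.37; 1.94e-09, and 0.00304), and cartilage markers higher in 10 of 12 by either adjustment (0.84; 4.12e-05, and 0.00438). Sex-linked genes differed in 5 of 5 members in Vhl/Rassf1a GFP, 1 higher and 4 lower by either adjustment (-1.63; 9.12e-12, 0.0333 with an estimated correlation and 0.0597 on ranks of DESeq2 statistics). As given for Vhl cells, a list test in 1 direction does not cover a shift in the shares of male and female cells. Whether these shares differ between WT GFP and Vhl/Rassf1a GFP libraries was not tested, and comparisons between these genotypes may hold such a difference. In all, 5319 genes differed in Vhl GFP (2857 higher and 2462 lower), 2664 in Rassf1a GFP (1557 and 1107) and 1913 in Vhl/Rassf1a GFP (1137 and 776). Genotype cannot be told apart here from the embryos or cultures used, since the labels do not state which libraries share them. In a fit of only the groups compared the counts were 1466 in Rassf1a GFP and 778 in Vhl/Rassf1a GFP, and with GC-corrected offsets 4002 and 3013.

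Calls were compared between genotypes to see which genes they share. Vhl and Vhl/Rassf1a cells shared 3468 called genes in the same direction, 1775 higher and 1693 lower, where independent lists would share 429 and 460, and 56 were called in opposite directions. WT and Rassf1a cells shared 45, 22 higher and 23 lower, where independent lists would share 0.258 and 0.146, and 0 were opposite. WT and Vhl cells shared 90, 63 higher and 27 lower (24.0 and 13.3 if independent), and 57 were opposite. WT and Vhl/Rassf1a cells shared 137, 90 higher and 47 lower (20.5 and 10.5), and 19 were opposite. Rassf1a and Vhl cells shared 38, 22 higher and 16 lower (5.395 and 6.37), and 10 were opposite. Rassf1a and Vhl/Rassf1a cells shared 48, 24 higher and 24 lower (4.61 and 5.03), and 6 were opposite. For opposite calls no number for independent lists was worked out, so whether they exceed it is not given.

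Called in the same direction in all 4 genotypes were 17 higher and 12 lower genes, several of them named here after their values were seen. The lower genes included Eml5, Mkrn2 and Ifrd2, the succinate receptor Sucnr1 (log2 fold change -6.16 in WT cells) and the unnamed transcript Gm37238 (-6.69), which went from 41.9 CPM ± 9.31 to 0.401 CPM ± 0.0400 in WT cells. The higher genes included the metalloprotease inhibitor Timp3 (0.30 in WT, 0.56 in Vhl, 0.26 in Rassf1a and 1.13 in Vhl/Rassf1a cells) and Flt1 (0.44, 0.48, 0.40 and 0.36). They also included the dopamine receptor Drd3, which had a mean of 0 CPM with GFP in WT, Vhl and Rassf1a cells and 0.0192 CPM in Vhl/Rassf1a cells, against 0.357, 1.67, 0.236 and 1.40 CPM with Cre.

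**Figure D4:**
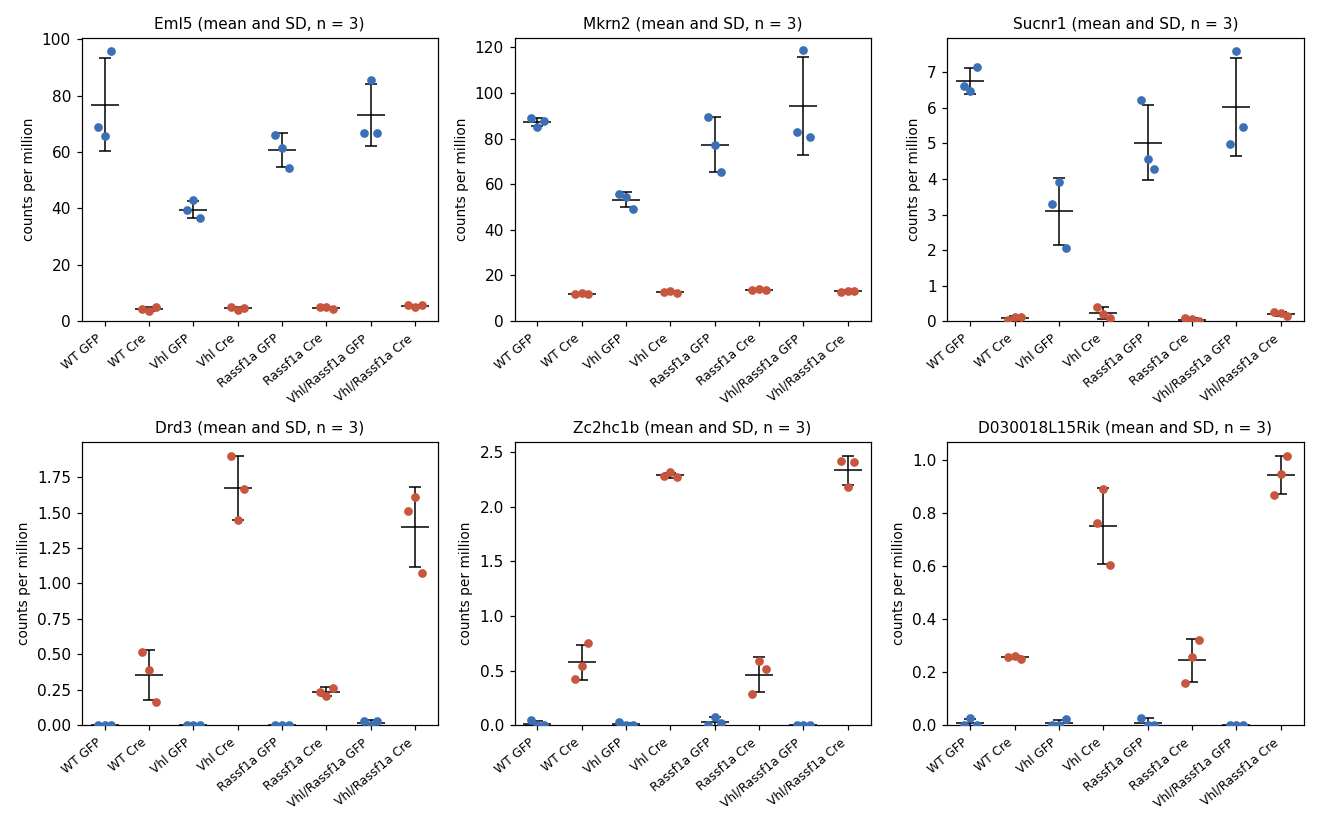
CPM in each of the 24 libraries, with the mean and SD of 3 per group, of Eml5, Mkrn2 and Sucnr1, lower with Cre in all 4 genotypes, and of Drd3, Zc2hc1b and D030018L15Rik, higher with Cre in all 4. These genes were picked after their values were seen.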

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

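The tests of reads from the delivered constructs, of a raised level in GFP cells and of a starting level were chosen only after the result was seen, as were the fits without the libraries that stood apart and with GC-corrected offsets.

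The Cre effect differed between Vhl and WT cells in 3846 genes by a test of the difference itself, as for every difference given here. Of the 100 splits of the samples drawn, 1, the real one, gave as many genes, and the highest other gave 2373. The splits draw Cre and GFP labels anew within each genotype, which takes the Cre effect itself away. They speak only to a count with no Cre effect at all. Equal Cre effects in both genotypes were not drawn, so the splits cannot exclude chance for the difference. The split with 2373 left 1 genotype unmixed and so kept the Cre effect of that genotype. Among the 80 splits that mixed every genotype the highest gave 0. The genes named by rule were Atp7b (6.53), H2-Ab1 (5.34), A2m (5.09), Car9 (4.61), Mgarp (4.53), Cox4i2 (4.41), Il1rn (-3.79), Vhl (-3.40), Islr (-2.96), Cebpa (-2.70), Iigp1 (-2.55) and Oasl2 (-2.30). The gene lists were glycolysis (median 1.19), other hypoxia genes (1.49), ccRCC transcripts (0.16), DNA repair (-0.31), mitosis and spindle (-0.82), secreted inflammatory factors (-0.32), skeletal muscle markers (0.59), mesothelial markers (0.71) and fibroblast markers (-0.35).

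Between Rassf1a and WT cells 1 gene differed by edgeR, Zmynd10 (3.99), chosen in this difference after its values were seen, against 544 at an unadjusted p under 0.05 and 1 by DESeq2. Of 100 splits drawn, 4 gave as many genes, the real one included, a share of under 0.05. A split that mixed every genotype also gave 1 gene, so a count of this size is weak ground for excluding chance. The count was 0 without WT GFP replicate 2. The highest other split gave 35. It left a genotype unmixed and so kept the Cre effect of that genotype, since splits that mixed every genotype gave at most 1.

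Between Vhl/Rassf1a and WT cells 2454 genes differed. Of 100 splits drawn, 1, the real one, gave as many, and the highest other gave 681. As above, splits take the Cre effect away, so they cannot exclude chance for a difference between Cre effects. The genes were Atp7b (6.50), A2m (5.56), H2-Ab1 (5.39), Ndufa4l2 (4.50), Car9 (4.41), Mgarp (4.36), Vhl (-3.44), Isg15 (-2.84), Oasl2 (-2.67), Usp18 (-2.37), Iigp1 (-2.32) and Gbp3 (-2.24). The lists were glycolysis (median 1.23), other hypoxia genes (1.52), ccRCC transcripts (0.27), DNA repair (-0.21), DNA replication (-0.34), mitosis and spindle (-0.30), amino acid response (-0.65), ribosome biogenesis (-0.34), skeletal muscle (0.39), fat (-0.62) and mesothelial markers (0.74). On ranks of DESeq2 statistics the calls of ccRCC transcripts (adjusted p = 0.0793) and skeletal muscle markers (0.0732) were lost, the latter also with no filter (0.102).

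Between Vhl/Rassf1a and Vhl cells 1010 genes differed. Of 100 splits drawn, 11 gave as many, the real one included, so chance cannot be excluded by this count. The highest other gave 4223, several times the real count. Each of the 10 other splits left 1 genotype unmixed, and so set its whole Cre effect against a mixed one. The 79 splits that mixed both genotypes gave at most 0. The share thus counts how often a Cre effect outlasted the draw, and does not test whether the Cre effects differ. The genes were Il1rn (1.77), Mmp3 (1.43), Pi15 (1.36), Mmp13 (1.23), Sned1 (1.22), Pamr1 (1.22), Myh2 (-1.59), Myh1 (-1.52), Apln (-1.48), Sfrp2 (-1.37), Kank4 (-1.23) and Kcnf1 (-1.23). The lists were mitosis and spindle (median 0.54), secreted inflammatory factors (0.33) and ribosome biogenesis (-0.25).

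The double effect differed from the sum of the single effects in 506 genes. The count was 336 without Rassf1a Cre replicate 1 and 337 without Vhl/Rassf1a Cre replicate 3. Of 100 splits drawn, 4 gave as many, the real one included, a share of under 0.05. The highest other gave 1265. The 3 others as large each left 1 genotype unmixed and so kept the Cre effect of that genotype. The 60 splits that mixed every genotype gave at most 0. As above, splits take Cre effects away and draw no additive effects, so this share cannot exclude chance for the difference from the sum. The genes were Il1rn (2.10), Mmp3 (2.08), Serpina3n (1.95), Pamr1 (1.72), Enpp2 (1.59), Prl2c2 (1.59; adjusted p = 0.0536 without Vhl Cre replicate 3), Myh1 (-2.07), Apln (-1.77), Myh2 (-1.73), Kcnf1 (-1.70), Sfrp2 (-1.48) and Ptprb (-1.28). The lists were mitosis and spindle (median 0.49), secreted inflammatory factors (0.38), matrix (0.33), heat shock (-0.12), ribosome biogenesis (-0.27) and fibroblast markers (0.26). Inflammatory, matrix and fibroblast lists rose with Cre in WT cells, which is added in this difference.

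For the Cre effects in WT, Vhl, Rassf1a and Vhl/Rassf1a cells, 209, 5991, 65 and 4919 genes, and for Vhl, Rassf1a and Vhl/Rassf1a GFP against WT GFP, 5319, 2664 and 1913 genes, each set of 6 libraries has 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes, and the highest other gave 0.

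A first pattern is the genes that went the same way with Cre in all 4 genotypes, WT included. The 12 lower genes moved together across the 12 GFP libraries, with a median pairwise correlation of 0.297, against a 95th percentile of 0.192 for random sets of genes, and of 0.194 against 0.126 without the libraries that stood apart. Drd3, Zc2hc1b and D030018L15Rik, near 0 with GFP, took shares of their summed counts that varied little more than sampling noise over the 12 Cre libraries (chi-square over degrees of freedom 1.51; D030018L15Rik 16.1% in Vhl and 26.4% in Rassf1a, Drd3 35.3% and 24.8%), while that sum ran from 0.946 CPM in Rassf1a to 4.72 CPM in Vhl cells. As a hypothesis, reads of the delivered GFP and Cre constructs may be counted for these genes. The first test came out as predicted for it, but genes that share any response of the cells would also move together. The 12 genes were picked from the same data, and the random sets were not. The first test therefore cannot decide, and the second does not exclude the hypothesis. No sequence of the constructs was available, and an effect of Cre or GFP on the cells' own genes was not tested and stays open.

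A second pattern is the lower interferon-stimulated genes with Cre in Vhl and Vhl/Rassf1a cells. A single GFP library with raised levels is argued against, since the median change stayed at or below -1.33 with any GFP library left out. A raised level in GFP cells that Cre removes in any altered genotype is argued against as well, since Vhl minus Rassf1a had a median of -1.44, with 30 of 34 genes lower. With an estimated correlation, though, the adjusted p of that difference was 0.262. A response to loss of Vhl may account for the pattern, as a hypothesis found and tested on the same data, and a response to delivery that differs between genotypes stays open as untested.

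The last pattern is the smaller fall of mitosis and spindle genes in Vhl/Rassf1a than in Vhl cells. The median difference was 0.509 without the libraries that stood apart and 0.511 with GC-corrected offsets, values that argue against either as the whole cause. A higher starting level in Vhl GFP is argued against, since Vhl GFP minus Vhl/Rassf1a GFP had a median of -0.426, with 34 genes lower. No biological explanation was tested. In Rassf1a cells the list had a median of 0.04 with 0 of 35 members called by edgeR (camera adjusted p = 0.0669). Counts of Rassf1 could not show the Rassf1a alteration itself. A difference in growth between the embryos or cultures used stays open, since the labels do not state which libraries share them.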

How the results depend on the processing

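The fits with GC-corrected offsets and without the 2 GFP libraries that stood apart were chosen after seeing the data. Not every alternative was run on every result. The fit without these 2 libraries covered only comparisons that use Rassf1a GFP or Vhl/Rassf1a GFP. A fit of only the groups compared left out the difference from the sum, and the replicate block left out comparisons of GFP libraries. Losses under these 3 alternatives therefore come from fewer results than the totals given next. Of 392 called values of named genes, 44 lost their call with at least 1 library left out, 31 in a fit of only the groups compared, 14 with a replicate block, 11 with no filter, 4 without the libraries that stood apart, 2 with GC-corrected offsets, 2 with DESeq2 and 1 with its size factors, and 0 changed sign. Of 165 called list results, 106 lost their call with an estimated correlation, 39 with at least 1 library left out, 28 with fry, 21 with DESeq2, 14 without the libraries that stood apart, 10 with no filter, 9 with GC-corrected offsets, 7 with only the groups compared and 1 with size factors. In Rassf1a cells the direction turned for nuclear oxidative phosphorylation genes (adjusted p = 0.929) and ribosomal proteins (0.386) without the libraries that stood apart, and for ribosomal proteins without Rassf1a GFP replicate 1 (0.559). With 1 library left out the adjusted p of ribosomal proteins ran from 3.055e-07 (without Rassf1a GFP replicate 3) to 0.559.

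With 1 library left out, counts ran from 87 to 187 in WT (87 without WT GFP replicate 1, 108 without WT GFP replicate 3, 124 without WT Cre replicate 2, 103 without WT Cre replicate 3), 5089 to 5320 in Vhl, 24 to 67 in Rassf1a (40 without Rassf1a GFP replicate 1, 24 without GFP replicate 2, 31 without Cre replicate 1, 29 without Cre replicate 2, 42 without Cre replicate 3) and 4055 to 4782 in Vhl/Rassf1a cells. Differences ran from 3368 to 3536 for Vhl and 2045 to 2624 for Vhl/Rassf1a against WT, 0 to 1 for Rassf1a against WT (0 without WT GFP replicate 2), 713 to 1186 for Vhl/Rassf1a against Vhl and 336 to 687 for the sum (336 without Rassf1a Cre replicate 1, 337 without Vhl/Rassf1a Cre replicate 3). GFP counts ran from 4356 to 4778, 2003 to 2579 and 1399 to 1964. Fewer samples were tested in each.

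Requiring a log2 fold change of at least 1 left 28, 1170, 20 and 807 genes in WT, Vhl, Rassf1a and Vhl/Rassf1a cells, 1009 and 522 for Vhl and Vhl/Rassf1a against WT, 157 for Vhl/Rassf1a against Vhl, 143 for the sum and 855, 466 and 410 between GFP libraries. It left 12, 16, 14, 11, 545 and 12 shared genes for WT with Vhl, Rassf1a and Vhl/Rassf1a, Vhl with Rassf1a and Vhl/Rassf1a, and Rassf1a with Vhl/Rassf1a. GC-corrected offsets gave 535 in WT, 209 in Rassf1a, 3990 for Vhl/Rassf1a against WT, 2261 against Vhl, 1345 for the sum, and 4002 and 3013 for Rassf1a and Vhl/Rassf1a GFP. Without the libraries that stood apart there were 112 in Rassf1a, 2 for Rassf1a against WT, 1856 for Vhl/Rassf1a against Vhl and 964 for the sum. A fit of only the groups compared, by edgeR, gave 12 in Rassf1a, 3008 in Vhl/Rassf1a, 0 for Rassf1a against WT, 631 for Vhl/Rassf1a against Vhl, and 1466 and 778 for Rassf1a and Vhl/Rassf1a GFP. In fits of all groups, Rassf1a against WT had 1 gene by DESeq2, and 544 by edgeR at an unadjusted p under 0.05. No filter gave 151 in Rassf1a and 22 for Rassf1a against WT. DESeq2 gave 103 in Rassf1a, and 72 and 62 genes shared by Rassf1a with WT and with Vhl. The cause was not tested.

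With a replicate block, counts were 121 in WT, 31 in Rassf1a and 318 for the sum, and shared genes 52, 27 and 77 for WT with Vhl, Rassf1a and Vhl/Rassf1a, 18 for Vhl with Rassf1a and 25 for Rassf1a with Vhl/Rassf1a. Libraries of the same number correlated at -0.0916 to 0.0347 after group means were removed and those of other numbers at -0.0753 to 0.0947, so the numbers do not pair them.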

Other observations

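Some genes had high counts in 1 library alone. Scrt2, a transcription factor of neurons, had 66656 counts in Vhl GFP replicate 3 and at most 186 in any other library, and Gpm6a, a neuronal membrane glycoprotein, 2437 in WT Cre replicate 1 and at most 13 elsewhere. Both were chosen after their values were seen.

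Set against WT and Vhl cells together, the Cre effect in Rassf1a and Vhl/Rassf1a cells together differed in 94 genes, a comparison made only after the result was seen. The smallest adjusted p were those of Nell2 (-0.52, SE 0.06, adjusted p = 0.000209), Sned1 (0.55, SE 0.07, adjusted p = 0.00142), Ptprb (-0.44, SE 0.06, adjusted p = 0.00142), Myh2 (-0.73, SE 0.10, adjusted p = 0.00176) and Zmynd10 (2.67, SE 0.38, adjusted p = 0.00176), all chosen after their values were seen. The values are means of Rassf1a minus WT and Vhl/Rassf1a minus Vhl, so a gene can pass through 1 of these alone. Taken singly, the first called only Zmynd10 and the second 1010 genes. Sned1 and Myh2 were at 1.22 and -1.59 in the second and were not called in the first. The 94 genes are thus not shown to change alike in both genotypes.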
